A study of Homo sapiens with 12 samples.

How the data were processed

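RNA from 12 samples of human bronchial epithelial cells, 2 for each of 3 EGFR forms at each of 2 oxygen levels, was labelled as biotinylated cRNA and read on Illumina bead arrays. The deposited table of raw signal holds the intensity of 47323 probes on each array on a linear scale, with no background subtracted, no detection p-values and no control probes. The authors' processed table holds log2 values that are quantile normalized between arrays, with a median of 3.11 on each array; within each array it ranks the probes as the raw table does (Spearman correlation 1), and how its background was corrected is not given in the sources used here. All 12 samples were used, and no sample column was left out. Groups follow the labels: WT, L858R or E746-E750 EGFR, aerobic at 21% oxygen or hypoxic at 0.1% oxygen for 24 h, with 2 arrays in each of the 6 groups. The replicate numbers of different groups share nothing but a number in the labels, so the fit was not paired.

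The raw intensities were background corrected with normexp (offset 50) and quantile normalized on the log2 scale with limma 3.58.1 in R 4.3.3. The plan fixed before the data were examined named neqc, which infers its controls from detection p-values; without these it could not be fitted, and normexp, planned as its alternative, became the main setting. A probe counted as detected on an array when it lay above percentile 99 of the array's noise peak, mirrored about its mode (density bandwidth 0.02 log2). Probes detected on at least 2 of the 12 arrays were kept, 22798 in all, of which 16771 carried a gene name. Names came from the reference of probes and genes: 30121 probes had a gene, 8 with several genes were left out, and 17202 had none and were not analysed here. Each gene was represented by its probe with the highest mean over the 12 arrays, which gave 12414 genes, 3380 of them with at least 2 kept probes. No genome build came with the probes used, so no positions are given.

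A model with a mean for each of the 6 groups was fitted with limma (lmFit and eBayes, 6 residual degrees of freedom), and all groups shared 1 estimate of the spread. Contrasts were hypoxic minus aerobic in each line, the differences between lines at each oxygen level, and the mutant response minus the WT response; a second model with line and oxygen gave hypoxia over all lines. P-values were adjusted by Benjamini-Hochberg over the 12414 genes within a contrast and called under 0.05. The tests are two-sided. The 29 gene lists, fixed with the plan, were tested with camera at a preset correlation of 0.01, adjusted over the lists within a contrast, and again with an estimated correlation. They cover HIF targets, glycolysis and glucose uptake, homologous recombination, the Fanconi anaemia pathway, non-homologous end joining, mismatch, base excision and nucleotide excision repair, DNA replication, the replication stress checkpoint, mitosis, p53 targets, ERK outputs, the EGFR family and ligands, the integrated stress and unfolded protein response, cholesterol and fatty acid synthesis, oxidative phosphorylation, ribosome biogenesis, NRF2 targets, interferon-stimulated genes, inflammatory cytokines, matrix proteases, and markers of basal, squamous, secretory and ciliated, and alveolar epithelium, mesenchymal cells, endothelium and leukocytes.

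Genes were named by a rule fixed in advance: in each comparison the 6 highest and 6 lowest called genes that were detected on both arrays of the brighter group and whose groups did not overlap, then up to 4 called members of each list (2 for an interaction), then VEGFA, BRCA1 and EGFR whether called or not. Some other genes of the rule had no probe named in the table used or were left out, and are not reported here. Symbols that stand for unnamed loci or reading frames, antisense transcripts and numbered families were passed over. Where neither array of the dimmer group detected a gene, its fold is a lower bound against the detection level, and in an interaction an undetected group was set to that level in the same way. Second probes of a gene are given with their own fit over all kept probes.

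The alternatives fixed with the plan were no background correction, median centring, cyclic loess, the authors' processed values, no filter, detection on all 12 arrays, the mean of a gene's probes, eBayes with trend and robust, only the arrays compared, the replicate number as a block, array weights, and each array left out in turn. Alternatives chosen after seeing the data were an offset of 16, array weights per group, the second probe of a gene, the 8 aerobic and WT hypoxic arrays alone, and leaving out the second replicates of both mutant hypoxic groups. In a fit with 1 array left out the lone array of its group is assumed to vary like the other groups.

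The model was tested on simulated data with the noise of the real arrays, 10 draws of 12414 genes, 200 of them changed. The relative noise was 0.312 to 0.698 in the other groups and 2.21 for the L858R hypoxic pair, placed in both of its arrays or, as 3.05, in replicate 2 alone. With it in replicate 2 alone, 57.5% to 63.9% of 2-fold changes were recovered in the comparisons of groups within a line or an oxygen level, 27.2% and 28.2% in the interactions and 89.1% over all lines. The false share of the calls was then at most 2.84% outside the contrasts that use the L858R hypoxic group, and 7.93% for hypoxia in L858R, 16% against WT and 25.4% against E746-E750 in hypoxia, and 1.74% in the L858R interaction. With the noise in both arrays the false share was 90%, 90.6%, 91.1% and 69.3% in those 4 contrasts and at most 2.52% in the others, and with no gene changed the medians of the calls were 1249.5, 1347.5, 1460 and 88. Array weights gave a median of 0 calls with no gene changed under either placement, and recovered 78.4% to 98.7% of 2-fold changes outside those 4 contrasts but at most 3.28% within them. On 290 unchanged lists of randomly drawn genes camera gave 2.41% under 0.05. The simulated genes varied independently, so this does not test the preset correlation on real lists, whose genes may vary together. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.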

Results

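Gene expression was measured on Illumina bead arrays in 12 RNA samples from human bronchial epithelial cells (HBEC), cells of the airway lining kept in a serum-free medium with EGF. The cells stably expressed 1 of 3 forms of the receptor EGFR: wild type (WT), L858R, a substitution in the kinase domain, or E746-E750, named in the labels by a stretch of kinase residues. Each line was kept aerobic at 21% oxygen or hypoxic at 0.1% oxygen for 24 h, which gave 6 groups of 2 arrays. The labels do not say whether the 2 samples of a group came from separate cultures, so every p-value measures only the spread between these samples, which may be technical. The upper quartile of raw intensity per array was 128 to 207, and 15011 to 19198 of the 47323 probes were detected. The number of arrays limits the precision. The series asks about EGFR mutation, hypoxia, radiation and the repair of breaks at replication forks, so the fixed gene lists cover hypoxia, DNA replication and DNA repair. Differences are on the log2 scale with their standard error, n = 2 arrays per group. P-values are adjusted over the 12414 genes tested, and a gene is called at an adjusted p under 0.05.

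The mutant hypoxic arrays differed from the rest in how the probes of a gene behaved. Over 3380 genes with at least 2 kept probes, the share whose 2 brightest probes had moved apart by more than 1 on the log2 scale from their aerobic mean was at most 0.118% on each aerobic array. It was 3.25% and 2.75% on the WT hypoxic arrays, 17.8% and 44.5% on the L858R hypoxic arrays, and 19.8% and 26.7% on the E746-E750 hypoxic arrays. For ACTB, the cytoskeletal actin gene, probe ILMN_1777296 read 13.88 to 14.40 on the aerobic and WT hypoxic arrays and 6.66 to 8.31 on the 4 mutant hypoxic arrays, while its other probes stayed at 13.56 to 14.52 on every array. L858R hypoxic replicate 2 stood apart as well. Across probes, which are not independent replicates, its correlation with its replicate was 0.856, against 0.984 to 0.997 in the other 5 pairs. It had the fewest detected probes, 15011.

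**Figure D1:**
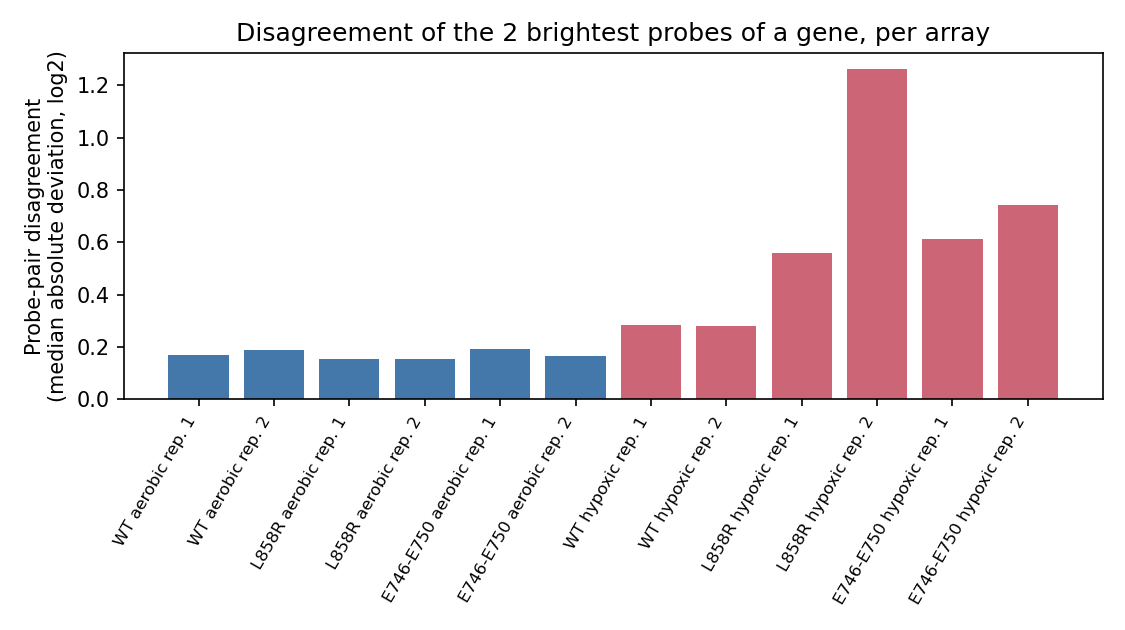
Disagreement of the 2 brightest probes of a gene on each of the 12 arrays, as the median absolute deviation (log2) over 3380 genes from the pair's mean difference on the aerobic arrays; blue bars are aerobic arrays and red bars hypoxic arrays. The WT hypoxic arrays reach 0.28, the other hypoxic arrays lie between 0.56 and 1.26, and no aerobic array exceeds 0.19.

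How low oxygen changed transcription was asked first in the WT line. After 24 h at 0.1% oxygen these cells had higher levels of targets of HIF, the oxygen-sensing transcription factors, and of genes for sugar breakdown and sterol synthesis, and lower levels of genes that build ribosomes. IGFBP3, a secreted binder of insulin-like growth factors, rose by 5.98 ± 0.33 (adjusted p = 3.66e-05), the glycolytic enzyme gene ENO2 by 4.73 ± 0.23 (adjusted p = 1.57e-05) and LOX, which cross-links collagen, by 4.61 ± 0.26 (adjusted p = 3.98e-05). TXNIP, an inhibitor of thioredoxin, changed by −3.65 ± 0.26 (adjusted p = 9.77e-05), the nucleolar gene NOP16 by −3.45 ± 0.19 and MAT2A, which makes the methyl donor S-adenosylmethionine, by −3.21 ± 0.14. Of 27 measured HIF targets 20 rose, and 23 did when adjusted over the list alone. HIF targets as a list had adjusted p = 3.31e-26, adjusted p = 0.0196 with an estimated correlation. They include ANKRD37 (5.32 ± 0.38), HILPDA (3.64 ± 0.14), which coats lipid droplets, and VEGFA (1.86 ± 0.31), the vessel growth factor. Of 23 glycolysis and glucose uptake genes 10 rose, or 12 adjusted over the list alone, with the glucose transporter gene SLC2A3 at 4.27 ± 0.13 and the glycogen-branching enzyme gene GBE1 at 2.45 ± 0.24. Glycolysis as a list had adjusted p = 2.5e-10, adjusted p = 0.0196 with an estimated correlation. Of 21 genes of cholesterol and fatty acid synthesis 10 rose, or 13 adjusted over the list alone, among them IDI1 (2.53 ± 0.33) and HMGCS1 (2.08 ± 0.31), enzymes of the sterol route, and the desaturase gene FADS2. Lipid synthesis as a list had adjusted p = 5.85e-10, adjusted p = 0.0196 with an estimated correlation. Of 20 ribosome biogenesis genes 15 fell, or 17 adjusted over the list alone, with RRS1 at −2.95 ± 0.26 and DKC1, a pseudouridine synthase gene, at −2.26 ± 0.23. Ribosome biogenesis as a list had adjusted p = 3.09e-13, adjusted p = 0.0267 with an estimated correlation. Among 17 p53 targets 4 rose, such as SESN1 at 1.05 ± 0.16. The p53 targets as a list had adjusted p = 0.00339, but adjusted p = 0.0582 with an estimated correlation. Among 16 base excision repair genes 5 fell, or 8 adjusted over the list alone, such as PARP1, a sensor of strand breaks, at −1.36 ± 0.20. Base excision repair as a list had adjusted p = 0.01, but adjusted p = 0.361 with an estimated correlation. Of the outputs of ERK signalling, a list that was not called, SPRY1 (1.96 ± 0.15) and FOS (1.87 ± 0.17) rose and MYC changed by −1.85 ± 0.22. In all, limma called 1568 genes, 641 up and 927 down, 356 and 464 of them by at least 2-fold. With median centring in place of quantile normalization the median of all genes moved from −0.02 to −0.12 and the share of called genes that rose from 40.9% to 22.9% (539 up, 1819 down). Relative to that median the list means stayed at 2.25 for HIF targets and −1.43 for ribosome biogenesis. The count was 535 or 583 without WT aerobic replicate 1 or 2 and 631 or 695 without WT hypoxic replicate 1 or 2. It was 4802, all 1568 genes included, without either L858R hypoxic replicate, since leaving out either takes that pair's difference out of the pooled spread. Each gene named so far kept its call when any 1 array was left out. They are only a part of the called genes under the naming rule. Many others under it, such as HK2 and LIG3, lost theirs at least once.

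In L858R cells the same exposure raised HIF targets and lowered ribosome biogenesis genes and some genes of DNA replication and mitosis. ENO2 rose by 4.54 ± 0.23 (adjusted p = 8.15e-06), LCE1B, a gene of the cornified layer of skin, by 4.03 ± 0.20 (adjusted p = 8.15e-06) and LCN2, which encodes an iron-scavenging secreted protein, by 3.45 ± 0.21. ANXA8, whose name covers near-identical gene copies, was at least 28.9-fold lower (adjusted p = 1.48e-06), a bound set by the level at which a probe counts as detected, since neither hypoxic array showed it. Its second probe gave −0.67 and did not pass. Of 27 HIF targets 21 rose and 1 fell, and among the former were ERO1A (3.29 ± 0.28), VEGFA (8.01-fold, adjusted p = 0.00029; second probe 2.89) and KDM3A (3.12 ± 0.24). HIF targets as a list had adjusted p = 5.64e-10, but adjusted p = 0.241 with an estimated correlation. Of 23 glycolysis genes 11 rose and 1 fell, with SLC2A3 up by 3.48 ± 0.13. Glycolysis as a list had adjusted p = 0.0171, but adjusted p = 0.242 with an estimated correlation. Of 20 ribosome biogenesis genes 12 fell, or 13 adjusted over the list alone, with NOP16 at −2.64 ± 0.19 (second probe −3.38) and BOP1 at −2.16 ± 0.14. Ribosome biogenesis as a list had adjusted p = 3.25e-08, but adjusted p = 0.241 with an estimated correlation. Among 35 DNA replication genes 7 fell and 3 rose, or 9 and 5 adjusted over the list alone. The helicase subunit genes MCM4 (−2.23 ± 0.18; second probe −1.54) and MCM7 (−2.59 ± 0.47; second probe −1.90) fell, and RRM2, which makes DNA precursors, was at least 3.6-fold lower. DNA replication as a list had adjusted p = 0.0486, but adjusted p = 0.242 with an estimated correlation. Among 26 mitosis genes 7 fell and 1 rose; HMMR (−1.74 ± 0.26) fell, though its second probe gave −0.59 and did not pass. Mitosis as a list had adjusted p = 0.0171, but adjusted p = 0.242 with an estimated correlation. Of 19 genes of the integrated stress and unfolded protein response 5 rose, with the chaperone gene DNAJB9 at 3.72 ± 0.25 and PPP1R15A at 2.02 ± 0.29. The stress response as a list had adjusted p = 0.0449, but adjusted p = 0.242 with an estimated correlation. MYC changed by −2.82 ± 0.22 and the immediate early gene EGR1 by −2.69 ± 0.44. Beside these groups, the 2 probes of a gene moved the same way in 74.4% of the 1126 called genes with a second probe, against 93% of 444 for hypoxia in WT. limma called 3416 genes, 1921 up and 1495 down, 1058 and 769 of them by at least 2-fold. The count was 607 with array weights and 0 when the 4 arrays compared were fitted alone (2343 at an unadjusted p under 0.05). With limma it was 1646 or 1567 without L858R aerobic replicate 1 or 2 and 8486 or 5591 without L858R hypoxic replicate 1 or 2, the latter sharing 3222 genes. HMMR lost its call with array weights, while the genes named kept theirs when any 1 array was left out. Many other called genes under the naming rule, such as HK2, lost theirs at least once. On simulated data with no change and the noise of the L858R pair in both of its arrays this model called a median of 1249.5 genes here, and the fit without replicate 2 called 6317.5, more than the 5591 observed. With that noise in replicate 2 alone both medians were 0. Median centring moved the median of all genes from 0.08 to −0.05 and the share that rose from 56.2% to 44.4% (1588 up, 1991 down). Relative to it the list means were 1.67 for HIF targets, −1.26 for ribosome biogenesis, −0.63 for DNA replication and −0.57 for mitosis.

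E746-E750 cells responded along the same lines. IGFBP3 rose by 5.80 ± 0.33 (adjusted p = 1.62e-05; second probe 5.79), ENO2 by 5.50 ± 0.23 (adjusted p = 2.84e-06) and LOX by 4.49 ± 0.26 (adjusted p = 1.81e-05). ANXA8 was at least 29.4-fold lower (second probe −0.84, not called), and AP1S1, a subunit of a vesicle adaptor, at least 28.9-fold lower (adjusted p = 8.58e-06). Of 27 HIF targets 21 rose, or 23 adjusted over the list alone, with PFKFB3 at 3.84 ± 0.15, HILPDA at 3.52 ± 0.14 and VEGFA at 2.94 ± 0.31 (second probe 3.07). HIF targets as a list had adjusted p = 1.46e-13, but adjusted p = 0.124 with an estimated correlation. Of 23 glycolysis genes 11 rose and 1 fell, with the hexokinase gene HK2 up by 3.82 ± 0.74. Glycolysis as a list had adjusted p = 0.000166, but adjusted p = 0.142 with an estimated correlation. Of 20 ribosome biogenesis genes 12 fell, or 16 adjusted over the list alone, such as NOP2 at −2.41 ± 0.24 and RRS1 at −2.34 ± 0.26. Ribosome biogenesis as a list had adjusted p = 4.23e-10, but adjusted p = 0.124 with an estimated correlation. Of 26 mitosis genes 9 fell, with CDC20, an activator of the anaphase-promoting complex, at −2.11 ± 0.37 and the centromere histone gene CENPA at −1.38 ± 0.26. Mitosis as a list had adjusted p = 0.000166, but adjusted p = 0.142 with an estimated correlation. MCM4 (−2.43 ± 0.18; second probe −2.04) and MCM6 (−1.90 ± 0.34) fell. The stress gene DNAJB9 rose by 2.89 ± 0.25 and ASNS, which makes asparagine, by 1.12 ± 0.17. Neither the replication nor the stress list was called. SPRY1 rose by 2.51 ± 0.15, and the EGFR ligand genes HBEGF and TGFA by 1.32 ± 0.19 and 1.31 ± 0.19. The 2 probes moved the same way in 74.8% of the 1049 called genes with a second probe. limma called 3231 genes, 1909 up and 1322 down, 992 and 687 of them by at least 2-fold. The count was 1605 or 1618 without E746-E750 aerobic replicate 1 or 2, 2105 or 1571 without E746-E750 hypoxic replicate 1 or 2, and 6997, all 3231 included, without either L858R hypoxic replicate, and the genes named kept their calls when any 1 array was left out. Many other called genes under the naming rule lost theirs at least once. Median centring moved the median of all genes from 0.09 to 0.23 and the share that rose from 59.1% to 77% (3400 up, 1018 down). Relative to that median the list means were 2.30 for HIF targets, −1.15 for ribosome biogenesis and −0.40 for mitosis.

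Across the lines, HIF targets and ribosome biogenesis genes moved together in the 3 responses, as the plot of list means shows. WT and L858R cells shared 410 genes called up and 481 called down, against 99.2 and 112 expected by chance, with 66 called in opposite directions. WT and E746-E750 cells shared 450 and 477, against 98.6 and 98.7, with 70 opposite. The 2 mutant lines shared 1335 and 1048, against 295 and 159, with none of the genes called in both going opposite ways. Across genes, which are not independent replicates, the log2 changes correlated at 0.442 between WT and L858R, 0.528 between WT and E746-E750 and 0.876 between the mutant lines. The mutant responses rest on the hypoxic arrays whose probes of a gene moved apart. Deviations of replicate 1 from its group mean also correlated at 0.745 between those 2 hypoxic groups. How much of the likeness comes from this was not separated. With the line as a covariate, limma called 4415 genes for hypoxia over all lines, 2362 up and 2053 down. The 2 probes moved the same way in 79.6% of the 1388 called genes with a second probe.

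**Figure D2:**
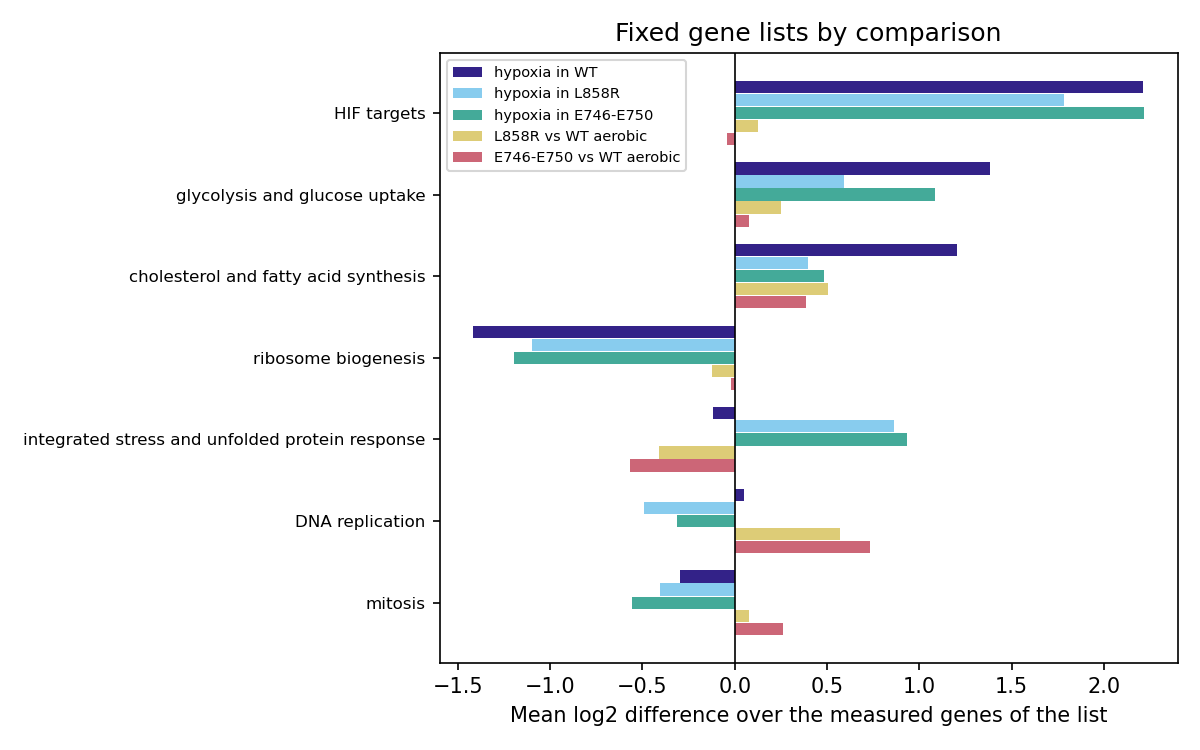
Mean log2 difference over the measured genes of 7 fixed lists, with 1 bar per comparison: hypoxic minus aerobic in each line, and each mutant line minus WT in aerobic cells. HIF targets reach 2.21 in WT, 1.78 in L858R and 2.22 in E746-E750, and DNA replication genes stand at 0.57 and 0.73 in the aerobic mutant lines; the bar for mitosis in aerobic E746-E750, 0.26, becomes −0.06 with median centring.

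What the EGFR forms changed in aerobic cells was asked by comparing each mutant line with WT at 21% oxygen. DNA replication genes were higher in both mutant lines, and genes of the integrated stress and unfolded protein response lower. In L858R cells 33 of 35 DNA replication genes were higher, with a mean of 0.57. No member passed over all genes tested and 6 did adjusted over the list alone. DNA replication as a list had adjusted p = 1.42e-17, adjusted p = 0.00403 with an estimated correlation. The stress list had a mean of −0.41, with 4 members lower adjusted over the list alone. The stress response as a list had adjusted p = 1.18e-06, adjusted p = 0.015 with an estimated correlation. Cholesterol and fatty acid synthesis had a mean of 0.51 (list adjusted p = 5.89e-08, adjusted p = 0.015 with an estimated correlation), and 5 members were higher adjusted over the list alone, led by INSIG1. Smaller means that also held with an estimated correlation were those of NRF2 targets, the antioxidant response (0.27, list adjusted p = 9.24e-05, adjusted p = 0.0221 with an estimated correlation), interferon-stimulated genes (0.25, 8.8e-05 and adjusted p = 0.0221) and oxidative phosphorylation (0.17, 0.00187 and adjusted p = 0.039). Glycolysis (0.25, list adjusted p = 0.00187), homologous recombination (0.15, list adjusted p = 0.00982) and the EGFR family and its ligands (−0.24, list adjusted p = 0.0401) were called, but with adjusted p = 0.141, adjusted p = 0.206 and adjusted p = 0.343 with an estimated correlation. INSIG1, a sterol sensor gene, was higher by 1.81 ± 0.17 (adjusted p = 0.0338; second probe 0.48). The other 5 called genes were the RNA-binding LSM3 (1.26 ± 0.15) and ZC3HAV1 (1.15 ± 0.13), the interleukin-33 receptor gene IL1RL1 (−1.73 ± 0.19), the RNA host gene SNHG17 (−1.58 ± 0.17) and CEBPG (−0.98 ± 0.12), each at adjusted p = 0.0444. These 6, 3 up and 3 down, were all that limma called (675 at an unadjusted p under 0.05). It called 0 without any 1 of the aerobic, WT hypoxic or E746-E750 hypoxic arrays (322 to 604 at an unadjusted p under 0.05). Without either L858R hypoxic replicate it called 756, these 6 included. Cyclic loess moved the share of called genes that were higher from 50% to 33.3% (3 up, 6 down).

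In aerobic E746-E750 cells all 35 DNA replication genes were higher than in WT, with a mean of 0.73. Of them 4 were called higher, or 12 adjusted over the list alone. DNA replication as a list had adjusted p = 4.73e-22, adjusted p = 0.00211 with an estimated correlation. They are the flap endonuclease gene FEN1 (2.08 ± 0.24, adjusted p = 0.0179; second probe 1.76), the sliding clamp gene PCNA (1.74 ± 0.21, adjusted p = 0.0202; second probe 0.56), MCM4 (1.59 ± 0.18, adjusted p = 0.0179; second probe 1.21) and the polymerase subunit gene POLE2 (0.81 ± 0.13, adjusted p = 0.047). The stress list had a mean of −0.57, with TRIB3 (−1.57 ± 0.19) and ASNS (−1.14 ± 0.17) called and 4 members lower adjusted over the list alone. The stress response as a list had adjusted p = 4.42e-07, adjusted p = 0.0137 with an estimated correlation. Among the larger single differences, SPOCK1, a matrix proteoglycan gene, was higher by 2.03 ± 0.27 (adjusted p = 0.0288). The receptor gene IGF2R differed by −1.98 ± 0.16 (adjusted p = 0.00699) and CBS, of the route from homocysteine to cysteine, by −1.89 ± 0.29 (adjusted p = 0.047). Oxidative phosphorylation had a mean of 0.22, which became −0.03 with median centring (list adjusted p = 0.000364, adjusted p = 0.0446 with an estimated correlation). Its members UQCRB and ATP5MC1 were called higher. Calls that were lost with an estimated correlation were cholesterol synthesis (mean 0.39, list adjusted p = 0.000154, adjusted p = 0.0543 with an estimated correlation), ERK outputs (−0.35, list adjusted p = 0.00104, adjusted p = 0.0882) and the EGFR family (−0.42, list adjusted p = 0.00665, adjusted p = 0.219). Lost as well were 4 lists whose mean changed sign with median centring: homologous recombination (0.24, then −0.01; list adjusted p = 0.00025, adjusted p = 0.0882 with an estimated correlation), mitosis (0.26, then −0.06; 5.36e-05 and adjusted p = 0.0709), matrix proteases (0.20, then −0.02; 0.00354 and adjusted p = 0.0709) and mesenchymal markers (0.18, then −0.02, with a median of 0.02; 0.0144 and adjusted p = 0.101). Median centring moved the median of all genes from −0.02 to −0.21, and relative to it the means were 0.61 for DNA replication, 0.19 for homologous recombination, 0.14 for mitosis and 0.18 for oxidative phosphorylation. The share of called genes that were higher went from 39.2% to 4.02% (27 up, 644 down), and with the series matrix values to 100% (1 up). limma called 51 genes, 20 up and 31 down, and no gene named here kept its call whichever array was left out. The count was 0 without either WT aerobic or either E746-E750 aerobic replicate (507 to 556 at an unadjusted p under 0.05 with limma). It was 2 without any 1 of the L858R aerobic, WT hypoxic or E746-E750 hypoxic arrays, and 1331, all 51 included, without either L858R hypoxic replicate.

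Whether the 2 mutant lines shared these aerobic differences was asked over all genes. Their differences from WT correlated at 0.754 across genes, with a covariance of 0.0519, against 0.537 and 0.00659 in simulated data in which the lines had nothing in common but the WT arrays. All 6 genes called in L858R were called the same way in E746-E750, and without L858R hypoxic replicate 2 the lines shared 236 up and 309 down, against 16.1 and 24.7 expected. With L858R set against 1 WT array and E746-E750 against the other, so that no array was shared, the covariance was 0.0433 to 0.0476. Both WT arrays are of the same line, so what is particular to that line or its culture enters both differences. A shared effect of the EGFR forms was not separated from it. Compared directly, IGF2R was higher in L858R than in E746-E750 (1.90 ± 0.16, adjusted p = 0.00982) and the repair gene MGMT, which removes alkyl groups from guanine, was at least 4.1-fold lower (adjusted p = 0.00759). KLHL4 (at least 1.9-fold higher, adjusted p = 0.0344) and FAM171A1 (−1.07 ± 0.12, adjusted p = 0.0369), the latter named after its values were seen, complete the 4 called genes, 2 up and 2 down. No list member passed, and all 9 lists called lost their call with an estimated correlation. Higher in L858R by mean were HIF targets (0.17, list adjusted p = 0.00599, adjusted p = 0.326 with an estimated correlation), glycolysis (0.17, 0.0175 and adjusted p = 0.256), ERK outputs (0.19, 0.00599 and adjusted p = 0.163), NRF2 targets (0.17, 0.0134 and adjusted p = 0.12) and interferon-stimulated genes (0.16, 0.00772 and adjusted p = 0.12). Lower by mean, but higher with median centring, were DNA replication (−0.16, then 0.19; 0.000349 and adjusted p = 0.12), mitosis (−0.18, then 0.19; 0.000349 and adjusted p = 0.12), ribosome biogenesis (−0.10, then 0.22; 0.0183 and adjusted p = 0.326) and mesenchymal markers (−0.17, then 0.05; 0.00194 and adjusted p = 0.12). Median centring moved the median of all genes from 0.02 to 0.26, and relative to it those 4 means were −0.07, −0.07, −0.04 and −0.21. The share of called genes that were higher went from 50% to 92.3% (12 up, 1 down), against 60% with no background correction or with cyclic loess. With limma the count was 0 without any 1 of the L858R or E746-E750 aerobic arrays (123 to 188 at an unadjusted p under 0.05). It was 1 without any 1 of the WT aerobic or E746-E750 hypoxic arrays, 2 without either WT hypoxic replicate and 110, the 4 included, without either L858R hypoxic replicate. None of the named genes kept its call throughout.

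The EGFR forms were then compared within hypoxia. In L858R cells at 0.1% oxygen single genes differed from WT while no list was called. SDF2L1 was higher by 3.47 ± 0.23 (adjusted p = 7.31e-05), DNAJB9 by 3.21 ± 0.25 (adjusted p = 0.000134), the chaperone gene HSPA5 by 1.77 ± 0.23, the disulfide isomerase gene AGR2 by 3.16 ± 0.24 (second probe 3.07) and DMBT1 by 3.03 ± 0.26. AKR1B10, an aldo-keto reductase gene induced by NRF2, was higher by 2.83 ± 0.16 and LCN2 by 2.88 ± 0.21. FADS2 was at least 15.9-fold lower (adjusted p = 1.02e-05), ANXA8 at least 22.8-fold lower (second probe −1.50, called), FOS differed by −3.00 ± 0.17 and EGR1 by −2.70 ± 0.44. The name RNA28SN5, for a 28S ribosomal RNA that is multi-copy in the genome, was at least 54.0-fold lower, with a second probe at −3.78. None of the 29 lists was called with camera (2 at an unadjusted p under 0.05), against 3 without L858R hypoxic replicate 2. The 2 probes moved the same way in 68% of the 835 called genes with a second probe. limma called 2595 genes, 1620 up and 975 down. The count was 167 with array weights, with which HSPA5 lost its call, and 0 with the 4 arrays compared alone (1600 at an unadjusted p under 0.05). With limma it was 1271 or 947 without WT hypoxic replicate 1 or 2, and 8402 or 4642 without L858R hypoxic replicate 1 or 2, the latter sharing 2457 genes. The genes named kept their calls when any 1 array was left out, but many other called genes under the naming rule did not. On simulated data with no change this comparison called a median of 1347.5 genes with the pair's noise in both L858R hypoxic arrays, or 6367.5 in the fit without replicate 2, above the 4642 observed. The median of all genes was 0.12, or 0.22 in the series matrix values.

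In hypoxic E746-E750 cells MAT2A was higher than in WT by 3.38 ± 0.14 (adjusted p = 6.12e-06), TXNIP by 2.84 ± 0.26, SPOCK1 by 2.82 ± 0.27, the p53 target TP53INP1 by 2.81 ± 0.40 (second probe 2.73) and DNAJB9 by 2.05 ± 0.25. FADS2 was at least 16.8-fold lower, ANXA8 at least 24.2-fold lower (second probe −1.67, called), and FOS differed by −2.65 ± 0.17. Of 19 homologous recombination genes 17 were higher, with a mean of 0.51, and 4 were called higher, or 5 adjusted over the list alone. NBN, of the complex that senses double-strand breaks, was higher by 1.28 ± 0.20 (adjusted p = 0.00355), but its second probe gave 0.41 and did not pass. The nuclease gene MUS81 was higher by 1.18 ± 0.13 (adjusted p = 0.000704), PALB2 by 1.09 ± 0.18 (adjusted p = 0.00457) and RAD54L by 0.91 ± 0.18 (adjusted p = 0.00975). That list had an adjusted p = 0.0363, but adjusted p = 0.839 with an estimated correlation and 0.107 without L858R hypoxic replicate 2. Of 19 ERK outputs 2 were called lower, FOS and EGR1 (−2.63 ± 0.44), and the list had a mean of −0.52. ERK outputs as a list had adjusted p = 0.0198, but adjusted p = 0.839 with an estimated correlation. The 2 probes moved the same way in 69.4% of the 697 called genes with a second probe. limma called 2139 genes, 1376 up and 763 down. The count was 1131 or 874 without WT hypoxic replicate 1 or 2, 1208 or 755 without E746-E750 hypoxic replicate 1 or 2, and 6182, all 2139 included, without either L858R hypoxic replicate. EGR1 lost its call without E746-E750 hypoxic replicate 2 (adjusted p = 0.0527), and RAD54L without that array or WT hypoxic replicate 2 (adjusted p up to 0.0931). Median centring moved the median of all genes from 0.12 to 0.21 and the share of called genes that were higher from 64.3% to 79.1% (2514 up, 664 down). Relative to it the mean was 0.43 for homologous recombination and −0.53 for ERK outputs.

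The 2 mutant lines resembled each other in hypoxia. They shared 929 genes called higher and 646 called lower than in WT, against 180 and 59.9 expected, with 4 opposite. Their differences correlated at 0.842 across genes with a covariance of 0.401, against 0.141 and 0.0147 in simulated data with the WT arrays alone in common, and the covariance was 0.386 to 0.387 with no WT array shared. The 4 arrays compared with WT here are those whose probes of a gene moved apart, and the deviations of replicate 1 from its group mean covary at 0.0602 between the 2 mutant groups, which the simulated data leave out. How much of the likeness comes from what these arrays have in common beside the EGFR form, or from the WT line as common reference, was not separated. Across oxygen levels the differences from WT hardly correlated across genes: 0.00368 for L858R and 0.0708 for E746-E750. Between the mutant lines, L858R had lower MB, the myoglobin gene (−2.58 ± 0.16, adjusted p = 0.00125, with 1 of the 2 L858R arrays detecting it and a second probe at −0.44, not called), MGMT (at least 3.3-fold lower, adjusted p = 0.00486) and IGFBP3 (−2.72 ± 0.33, adjusted p = 0.0238; second probe −2.76). It had higher AGR2 (1.81 ± 0.24, adjusted p = 0.0274; second probe 1.73), LCN2 (1.56 ± 0.21, adjusted p = 0.0276) and DMBT1 (2.04 ± 0.26, adjusted p = 0.0238). DNA replication genes had a mean of −0.35, with no member called and 2 lower adjusted over the list alone (list adjusted p = 0.0379, but adjusted p = 0.378 with an estimated correlation), and without L858R hypoxic replicate 2 there were 4 called lists in place of 1. limma called 59 genes, 21 up and 38 down, and 0 with array weights (262 at an unadjusted p under 0.05) or with the arrays compared alone (197). The count was 3 without any 1 of the aerobic or WT hypoxic arrays, 1 without either E746-E750 hypoxic replicate, and 7367 or 1795 without L858R hypoxic replicate 1 or 2. Of the genes named here MB alone kept its call whichever array was left out. With the pair's noise in both L858R hypoxic arrays simulated data with no change gave a median of 1460 calls here, and 6440.5 in the fit without replicate 2, above the 1795 observed. The share of called genes that were higher went from 35.6% to 46.9% with cyclic loess (38 up, 43 down) and to 20% in the series matrix values (3 up, 12 down).

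Whether the response to hypoxia itself differed between lines was tested as the mutant response minus the WT response. TXNIP, which fell in WT, had a difference of 4.49 ± 0.36 in L858R (adjusted p = 0.00043) and 4.55 ± 0.36 in E746-E750 (adjusted p = 0.000458). FADS2 rose in WT and was at least 5.2-fold lower after hypoxia in each mutant line, so that its response was at least 22.2-fold lower than that of WT in L858R and at least 22.5-fold lower in E746-E750. FOS, which rose in WT, had differences of −3.36 ± 0.24 and −2.72 ± 0.24. The stress genes went the other way. SDF2L1, which changed by −1.50 ± 0.23 in WT, had a difference of 3.23 ± 0.33 in L858R, and DNAJB9 of 3.53 ± 0.36 and 2.70 ± 0.36. Of the 19 genes of the integrated stress and unfolded protein response 7 had a larger response in L858R and 6 in E746-E750, or 10 and 8 adjusted over the list alone, with means of 0.98 and 1.05. Part of this is the lower aerobic level of the mutant lines, at −0.41 and −0.57 against WT, and in hypoxia the list stood at 0.57 and 0.49, not called. The stress response as a list had adjusted p = 0.00133 and 0.000609, but adjusted p = 0.128 and adjusted p = 0.105 with an estimated correlation. DNA replication genes had means of −0.54 in L858R, 4 of them called, and −0.36 in E746-E750, 3 called, the latter mean turning to 0.16 with median centring. The list was higher in the aerobic mutant lines, by 0.57 and 0.73, and stood at 0.03 and 0.37 against WT in hypoxia, not called. Of these RRM2 was called in both, its response at least 3.9-fold and 4.7-fold lower than that of WT. DNA replication as a list had adjusted p = 0.00292 and 0.00827, but adjusted p = 0.171 and adjusted p = 0.18 with an estimated correlation. Cholesterol and fatty acid synthesis had means of −0.80 and −0.72, with 2 and 3 members called, after aerobic differences of 0.51 and 0.39. Lipid synthesis as a list had adjusted p = 0.00539 and 0.00297, but adjusted p = 0.177 and adjusted p = 0.18 with an estimated correlation. In L858R the means were −0.43 for HIF targets, 5 of them called, or 6 adjusted over the list alone (list adjusted p = 0.0107, but adjusted p = 0.552 with an estimated correlation), and −0.79 for glycolysis, 2 called (list adjusted p = 0.0156, but adjusted p = 0.399 with an estimated correlation and 0.188 without L858R hypoxic replicate 2). In E746-E750 mitosis had a mean of −0.26 after an aerobic difference of 0.26, and of 0.29 with median centring, with no member called (list adjusted p = 0.0138, but adjusted p = 0.433 with an estimated correlation). VEGFA had differences of 1.14 ± 0.44 (adjusted p = 0.156) and 1.07 ± 0.44 (adjusted p = 0.202), which did not pass. The 2 probes moved the same way in 77.4% of the 336 called genes with a second probe in L858R and 73.1% of 338 in E746-E750. The shares were 72.46% and 64.41% among genes called up, lower than the 82.25% and 82.61% among genes called down. The interactions shared 311 genes up and 287 down, against 22.1 and 11.7 expected, with 1 opposite. They correlated at 0.854 across genes with a covariance of 0.454, against 0.176 and 0.0215 in simulated data with the WT arrays alone in common. With no WT array shared the covariance was 0.431 to 0.435. The WT line is still the reference of both, so what is particular to it enters both interactions.

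For L858R 923 genes were called in that test, 514 up and 409 down, against 208 with array weights and 203 with the 8 arrays compared alone. The count was 274 or 264, 263 or 236, 511 or 511, 518 or 319, 7479 or 3477 and 593 or 593 without replicate 1 or 2 of WT aerobic, L858R aerobic, E746-E750 aerobic, WT hypoxic, L858R hypoxic and E746-E750 hypoxic in that order, and all 923 genes were among the 3477. Simulated data with no change and the pair's noise in both L858R hypoxic arrays gave medians of 88 calls and, without replicate 2, 4675.5. For E746-E750 889 genes were called, 533 up and 356 down. The counts in the same order were 249 or 247, 517 or 517, 237 or 292, 464 or 349, 4744 or 4744 and 474 or 264, and all 889 genes were among the 4744. The genes named so far for these interactions, VEGFA apart, kept their calls when any 1 array was left out. Many other called genes under the naming rule lost theirs at least once. Median centring moved the median of all genes from 0.12 to 0.06 for L858R and from 0.14 to 0.44 for E746-E750. The share of called genes that were up in E746-E750 went from 60% to 91.6% (2829 up, 260 down), or to 48.9% with cyclic loess (426 up, 445 down). For L858R it went from 55.7% to 67.8% (863 up, 410 down). Relative to these medians the stress list stood at 0.82 and 1.01, DNA replication at −0.61 and −0.28, cholesterol synthesis at −0.92 and −0.69, and mitosis in E746-E750 at −0.15.

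DNA repair genes were examined because the series concerns breaks at replication forks. Homologous recombination genes had means of 0.03 in the WT response to hypoxia, with 1 member up and 1 down, 0.25 in L858R (4 up, 1 down) and 0.30 in E746-E750 (4 up), and the list was not called in any of these. MUS81 rose by 1.03 ± 0.13 in E746-E750, and its response exceeded that of WT by 1.39 ± 0.18 there (adjusted p = 0.00424). BRCA1 was not called in any comparison, with responses of 0.23 ± 0.28 in WT, 0.58 in L858R and −0.07 in E746-E750. Base excision repair genes that fell in the mutant lines include OGG1, which removes oxidized guanine, at −1.57 ± 0.16 in L858R and −1.79 ± 0.16 in E746-E750, each with 1 of 2 hypoxic arrays detecting it. UNG, which removes uracil, changed by −1.64 ± 0.15 in L858R, with a second probe at −0.19 that did not pass. Other members went the other way. Relative to the WT response OGG1 stood at −0.93 in L858R and −1.14 in E746-E750, but MBD4 at 1.73 in L858R and NEIL2 at 1.45 in E746-E750. The list was not called for hypoxia in either mutant line. On the mutant hypoxic arrays the probes of a gene had moved apart. Neither the falls nor the rises there, MUS81, MBD4 and NEIL2 included, can therefore be read as changes of the transcripts alone. Among the repair lists, the Fanconi anaemia pathway (lowest adjusted p over 11 comparisons 0.505), non-homologous end joining (0.252), mismatch repair (0.199), nucleotide excision repair (0.584) and the replication stress checkpoint (0.131) were called in none. The other uncalled lists were inflammatory cytokines (0.079) and the markers of basal (0.107), squamous (0.0716), secretory and ciliated (0.0901) and alveolar (0.572) epithelium, of endothelium (0.415, 1 gene) and of leukocytes (0.332).

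EGFR itself was read by 3 kept probes. The brightest, ILMN_1798975, was not called in any comparison. It stood at 0.77 ± 0.34 for hypoxia in WT and at −0.25 and −0.49 for aerobic L858R and E746-E750 against WT. In hypoxic L858R and E746-E750 against WT it stood at −0.37 and −0.43. A second probe, ILMN_1696521, rose by 1.29 ± 0.31 with hypoxia in WT (adjusted p = 0.034) and was lower in hypoxic L858R (−2.30 ± 0.31, adjusted p = 0.00156) and E746-E750 (−2.55 ± 0.31, adjusted p = 0.000925). Its aerobic differences of −0.999 and −1.19 did not pass, nor did its interactions of −1.30 and −1.36 (adjusted p = 0.114 and 0.105). It was not rerun with arrays left out, and its hypoxic differences from WT rest on the mutant hypoxic arrays, whose probes of a gene moved apart. The third, ILMN_1728858, was detected on 2 arrays and not called. Where these probes lie relative to the expressed EGFR constructs is not given in the sources used here, so their levels do not measure how much of each form the cells made.

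**Figure D3:**
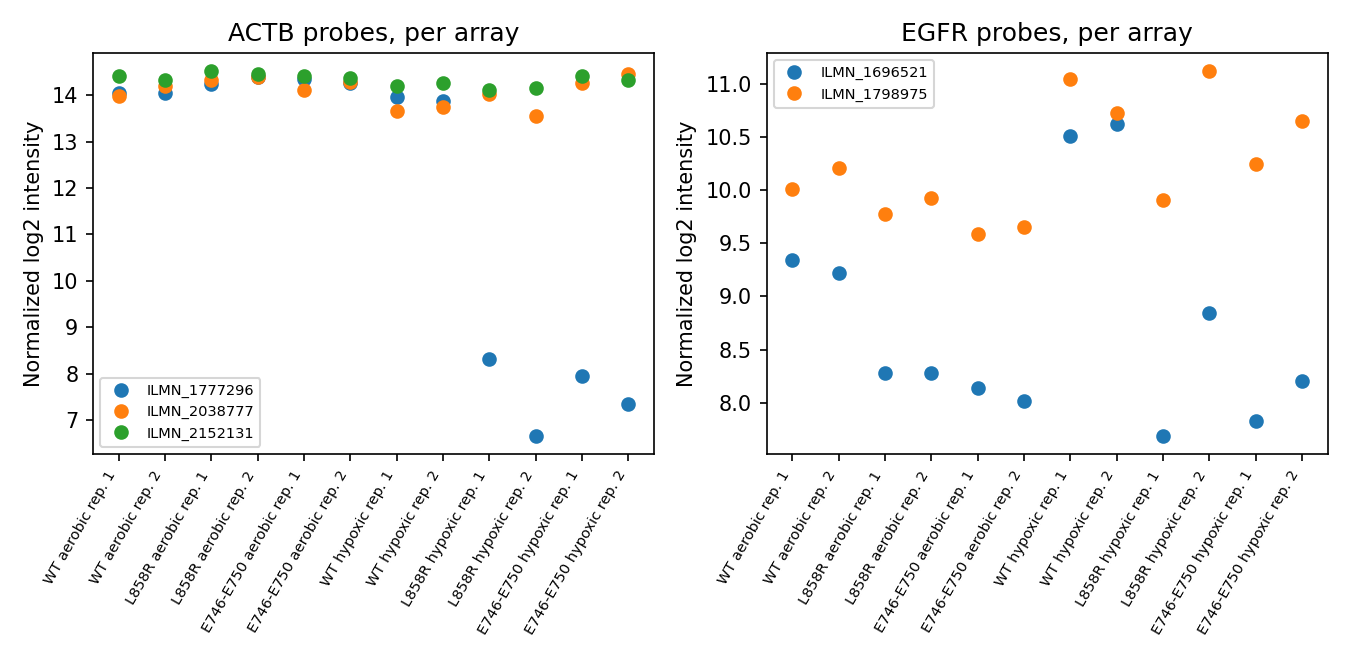
Normalized log2 intensity of each ACTB probe (left) and of the 2 brighter EGFR probes (right) on each of the 12 arrays, 1 point per array. ACTB probe ILMN_1777296 reads 6.66 to 8.31 on the 4 mutant hypoxic arrays and 13.88 to 14.40 elsewhere, and EGFR probe ILMN_1696521 is highest on the WT hypoxic arrays, at 10.51 and 10.62.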

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

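Of the tests in this part, the second probes of single genes, the estimates from separate arrays, the genes kept under other scalings and the hypoxic levels of the stress genes were chosen after the results were seen; the others were set down before.

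The response to hypoxia differed between lines by the test of the difference itself, in 923 genes for L858R against WT and 889 for E746-E750 against WT. For L858R the genes with the highest differences on the log2 scale were TXNIP (4.49), DNAJB9 (3.53), IL1RL1 (3.53), SDF2L1 (3.23), LCN2 (3.20) and CRELD2 (3.15), and those with the lowest were RNA28SN5 (−5.90), PGAM1 (−5.57), ANXA8 (−5.14), FADS2 (−4.74), RPL29 (−4.71) and AP1S1 (−4.61). For E746-E750 they were TXNIP (4.55), IL1RL1 (3.33), MAT2A (3.11), SLC30A1 (2.96), SNHG17 (2.84) and DNAJB9 (2.70), and RNA28SN5 (−6.35), PGAM1 (−5.77), RPL29 (−5.28), ANXA8 (−5.17), AP1S1 (−4.89) and SERF2 (−4.83). Some of these are fitted values of genes that neither array of a group detected, and only a bound can be read from them. The responses were lower than in WT by at least 55.8-fold for RNA28SN5, 27.8-fold for ANXA8 and 22.2-fold for FADS2 in L858R, and by at least 71.4-fold for RNA28SN5, 28.3-fold for ANXA8 and 24.8-fold for AP1S1 in E746-E750. That of IL1RL1, undetected in hypoxic WT cells, was at least 9.8-fold and 8.6-fold higher. The calls of PGAM1 (adjusted p = 0.0403 and 0.0355) and SERF2 (adjusted p = 0.0409) were lost when any of 10 single arrays was left out; the second probe of PGAM1 gave −6.08 and −6.09, and that of SERF2 −0.30.

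These differences were weighed against probe-level loss of signal, an array apart from the rest, and brightness scaling. limma called 1568 genes for hypoxia in WT, 3416 in L858R and 3231 in E746-E750, but array weights gave 5094, 607 and 6389, and the arrays compared alone 4952, 0 (2343 at an unadjusted p under 0.05) and 6189, so a wider response than that of WT is not shown for L858R. The difference from WT was estimated from 2 separate sets of arrays, 1 array per group in each. Over the 8 ways to split the arrays the 2 estimates correlated across genes at 0.784 to 0.846 for E746-E750 and 0.328 to 0.485 for L858R, so a single array does not account for the whole of either difference, while its share in L858R stays open. Of the 923 and 889 genes, 87.2% and 83.1% kept their call and direction with cyclic loess and 68.8% and 81.9% with median centring, so quantile scaling does not account for most of these calls; with the series matrix values, whose background differs too, 58.3% and 60.1% did. Across genes, the correlation of the changes of a gene's 2 brightest probes dropped from 0.782 for hypoxia in WT to 0.375 and 0.343 in the interactions, by at least 0.407, which is what loss of part of each transcript would give and is consistent with broken RNA in the 4 mutant hypoxic samples. Use of other transcript ends or isoforms by mutant cells in hypoxia could also part the probes of a gene. The array codes in the labels run from A to L in the order of the groups, with the 4 mutant hypoxic arrays last. Array order and group therefore cannot be told apart. The biological difference the design names, the EGFR form, stays open as untested, since these are the same 4 samples. The ribosomal RNA probes named RNA28SN5 and RNA18SN5 and 1 ACTB probe are lower in the same samples. The ACTB probe changed by −6.84 and −6.67 with hypoxia in the mutant lines. The other 2 changed by −0.57 and −0.34 in L858R, both called, and by 0.16 and −0.02 in E746-E750. The probes of GAPDH, a glycolysis gene, read 13.86 to 14.55 on L858R hypoxic replicate 1 and both E746-E750 hypoxic arrays. On L858R hypoxic replicate 2 they read 11.80, 13.46 and 12.05, so GAPDH shows no common loss over the 4 samples.

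That stress and chaperone genes responded more in the mutant lines was weighed against the same loss of signal, which lowers a probe. Of list members called with a larger response, 5 of 7 in L858R and 3 of 6 in E746-E750 were called above WT in hypoxia. None was called lower. Their choice by a larger response favours this outcome, since that response contains the hypoxic difference from WT. Loss of a probe's own signal would not raise it, but probes parted more among genes called upward on these arrays. The second probe had the same sign in 62.45% (L858R) and 64.05% (E746-E750) of genes called higher than WT in hypoxia. Among those called lower the shares were 75.94% and 77.62%. The brightest probe was chosen by its mean over all arrays, these included, so a probe that lost signal there is less likely to be chosen. These shares therefore do not decide whether the rises are of the transcripts. The members called higher in both lines include SDF2L1 (3.47 ± 0.23 against WT in hypoxic L858R), DNAJB9 (3.21 ± 0.25 and 2.05 ± 0.25) and HSP90B1 (1.11 ± 0.14 and 0.65 ± 0.14). In L858R the call of HSP90B1 is lost with array weights and those of all 3 with the arrays compared alone. For TRIB3 and ASNS, called with a larger response in both lines but not in hypoxia, the aerobic differences from WT were −1.57 and −1.14 in E746-E750, both called, and −1.40 and −0.78 in L858R, which did not pass (adjusted p = 0.0677 and 0.204). The list as a whole was lower in the aerobic mutant lines (means −0.41 and −0.57) and was not called in hypoxia (0.57 and 0.49). Of the 3 list members with 2 kept probes, 2 moved the same way with both probes in the L858R interaction, too few to decide. Loss of a member's own signal in the hypoxic mutant samples would make its response smaller. Other effects of the parted probes and a biological response cannot be told apart for these genes. The list's call is lost with an estimated correlation (adjusted p = 0.128 and 0.105).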

How the results depend on the processing

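Of the alternatives here, an offset of 16, group weights, the second probe, the 8 arrays alone and leaving out both second mutant hypoxic replicates were chosen after seeing the data; the others were fixed before. Of the 56 called results for a list in a comparison, 1 lost its call with no background correction, 5 in the series matrix values and 43 with an estimated correlation. Among single genes named in a comparison, those that kept direction but lost their call numbered 151 with array weights, 217 with the arrays compared alone, 100 in the series matrix values, 68 with median centring, 52 with cyclic loess, 42 with the mean of the probes, 36 with trend and robust, 32 with no filter, 32 with an offset of 16, 19 with detection on all arrays and 17 with no background correction. Over all single arrays left out, 5177 such results stayed, 1517 lost their call and 26 gained one. Counts are of called genes and the cause was not tested unless stated. Signal over background limits what can be read: 15011 to 19198 probes per array were above the noise, and a gene below it in a whole group gives a bound only. The planned neqc correction was not run, since it needs detection p-values.

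With 1 array left out the counts ranged from 535 to 4802 for hypoxia in WT, 1567 to 8486 in L858R and 1571 to 6997 in E746-E750; from 0 to 756 for aerobic L858R against WT, 0 to 1331 for E746-E750 against WT and 0 to 110 between the mutant lines; from 947 to 8402, 755 to 6182 and 1 to 7367 for the same comparisons in hypoxia; and from 236 to 7479 and 237 to 4744 for the L858R and E746-E750 interactions. The construction shows a cause of the high ends: without an L858R hypoxic array that pair no longer widens the pooled spread, and without replicate 1 the outlying replicate 2 also stands alone for its group. The low ends come from fits that leave a compared group with 1 array or the spread with fewer pairs. Without L858R hypoxic replicate 2 the called lists went from 0 to 3, 2 to 1 and 1 to 4 in the hypoxic comparisons of L858R with WT, E746-E750 with WT and the mutant lines.

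Taken in the order hypoxia in WT, L858R and E746-E750, then L858R against WT, E746-E750 against WT and L858R against E746-E750 in aerobic and in hypoxic cells, then the L858R and E746-E750 interactions, the arrays compared alone gave 4952, 0, 6189, 1942, 2654, 773, 0, 4469, 0, 203 and 4205. Where limma gave 0 there, 2343, 1600 and 197 genes had an unadjusted p under 0.05. Array weights gave 5094, 607, 6389, 1814, 2330, 517, 167, 5024, 0 (262 at an unadjusted p under 0.05), 208 and 4449 in that order and 7531 for all lines, and group weights 5094, 604, 6389, 1814, 2335, 517, 167, 5023, 0 (261), 208 and 4445. Without both second mutant hypoxic replicates the counts were 5641, 6359, 6499, 1365, 2104, 270, 5538, 5497, 978, 4549 and 4529, with 3, 1 and 5 lists called in the hypoxic comparisons. The 8 arrays alone gave 5641 for hypoxia in WT and 1365, 2104 and 270 in the aerobic comparisons.

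Median centring gave 2358 for hypoxia in WT, 24, 671 and 13 in the aerobic comparisons, 153 between the mutant lines in hypoxia and 3089 for the E746-E750 interaction. No background correction gave 12 for aerobic L858R against WT. An offset of 16 gave 0 there (597 at an unadjusted p under 0.05 with limma) and 25 for E746-E750 against WT. The series matrix values gave 0 (604), 1 and 2 in the aerobic comparisons and 15 between the mutant lines in hypoxia. Cyclic loess gave 18 for aerobic E746-E750 against WT, and no filter 78 there and 7 between the aerobic mutant lines. Detection on all arrays, which tests fewer genes, gave 1, 33 and 1 in the aerobic comparisons, 36 between the mutant lines in hypoxia, and 586 and 506 for the interactions; with it LIG3 for hypoxia in WT turned to 0.09 and FN1 in hypoxic L858R against WT to 0.29, another probe then standing for the gene. Trend and robust gave 1 and 19 for aerobic L858R and E746-E750 against WT.

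The mean of the probes gave 10 for aerobic L858R against WT and 93 between the mutant lines in hypoxia, and turned genes whose probes part. They are UQCRB (0.03) and TXNRD1 (−0.00) for hypoxia in L858R, SDHA (−1.09) and TXNRD1 (−0.57) for hypoxia in E746-E750, XRCC6 (−0.25), SQLE (−0.46), SDHA (−0.50) and TXNRD1 (−1.03) in hypoxic L858R against WT, and PKM (−1.42), SDHA (−0.90) and TUBA1A (−1.40) in hypoxic E746-E750 against WT.

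With the replicate number as a block limma gave 0 (677 at an unadjusted p under 0.05), 16 and 2 in the aerobic comparisons and 32 between the mutant lines in hypoxia. Over the 15 pairs of groups the deviations of replicate 1 correlated across genes at −0.199 to 0.745, 4 above 0.1 and 5 below −0.1, so the numbers were not taken to pair the samples. The 0.745 is between the L858R and E746-E750 hypoxic groups, and the next highest is 0.206. Those 2 groups deviate together with a covariance of 0.0602, which the simulated values leave out, against 0.401 between their differences from WT and 0.454 between the interactions. With the block 31 single genes and 1 list lost their call.

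With an estimated correlation camera called 0 lists for hypoxia in L858R (5 at an unadjusted p under 0.05) and in E746-E750 (5), 3 for aerobic E746-E750 against WT, 0 between the aerobic mutant lines (6), 0 for hypoxic E746-E750 against WT (1), 0 between the hypoxic mutant lines (3), and 0 (3) in each interaction.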

Other observations

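The second probes and the comparison of single aerobic arrays were chosen after the results were seen; the other tests in this part were set down before.

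Some single genes changed with hypoxia although their lists were not called for it in any line. Of the squamous markers, the cornified envelope gene CNFN rose by 1.48 ± 0.26 in E746-E750, FLG, the filaggrin gene, was at least 8.0-fold higher in L858R and at least 3.9-fold higher in E746-E750, and the calprotectin gene S100A9 changed by −2.61 ± 0.38 and −2.49 ± 0.38. Of the NRF2 targets, HMOX1, which breaks down heme, rose by 1.32 ± 0.15 in E746-E750, NQO1 changed by −1.10 ± 0.16 there, and AKR1B10 rose by 1.76 ± 0.16 in L858R, where its response exceeded that of WT by 1.90 ± 0.22 (adjusted p = 0.00234). TNFAIP3, a brake on NF-kB signalling, rose by 2.76 ± 0.19 in WT and by 1.33 ± 0.19 and 1.60 ± 0.19 in the mutant lines. SPARC, a matrix protein gene, rose by 1.38 ± 0.15 in WT and 1.16 ± 0.15 in E746-E750. The L858R values carry the limits of its hypoxic arrays: the calls of S100A9 and TNFAIP3 are lost there with array weights.

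Of 2 fatty acid desaturase genes in the mutant lines, FADS1 rose by 1.68 ± 0.16 in L858R and 2.07 ± 0.16 in E746-E750, while FADS2, which acts before it in the same pathway, was at least 5.2-fold lower in each. Each has 1 kept probe. Of 17 p53 targets 10 rose and 2 fell in L858R and 7 rose and 2 fell in E746-E750, and the list was not called in either (adjusted p = 0.0717 and 0.179). Among them are TP53INP1, up by 3.11 ± 0.40 and 3.57 ± 0.40 (second probes 3.79 and 3.48), and BAX at −2.18 ± 0.39 and −2.69 ± 0.39 (second probes −0.52, not called, and −0.96). The rise of FADS1 and the fall of FADS2 and BAX are seen on the 4 mutant hypoxic arrays. There the 2 brightest probes had moved apart in 17.8% to 44.5% of the genes with at least 2. These shifts therefore cannot be read as changes of the transcripts alone. For hypoxia in L858R and E746-E750 the 2 probes moved the same way in 68.27% and 68.6% of genes called up. Among genes called down the shares were 81.49% and 83.22%. MDM2 was lower than in WT in hypoxic L858R (−1.85 ± 0.17) and E746-E750 (−1.90 ± 0.17), though in L858R its call is lost with array weights.

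The higher DNA replication genes of the aerobic mutant lines were tested against an effect of a single array. Over the 8 pairs of a mutant and a WT aerobic array the mean of the list differed by 0.514 to 0.790, and between replicates of an aerobic group by at most 0.070, so a single array does not account for it. Scaling left the direction as well, with means of 0.59 and 0.41 under median centring and 0.77 and 0.98 in the series matrix values. A difference in cell cycle between the cultures may underlie it, though mitosis genes had means of 0.08, not called, and 0.26, or −0.06 with median centring. With 2 samples per line, each line's EGFR form and its culture cannot be separated.

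For hypoxia over all lines, 1 of 100 splits of the 12 arrays into 6 and 6, the real one, gave as many called genes as the 4415 observed; the highest other split, with 5 of the 6 hypoxic arrays on one side, gave 2622, and the median of the others was 0. A chance division of single arrays is thus an unlikely source if the 2 samples of a group are separate. The labels do not say so, and if these samples are technical the splits cannot exclude chance.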
